A study of Mus musculus with 3 samples.

How the data were processed

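RNA levels were measured in mouse embryonic stem (ES) cells on 3 Agilent 1-colour (Cy3) oligonucleotide arrays, each hybridised with labelled RNA of 1 sample. The labels put 2 samples in the Tet1 knockout group (KO 4 and KO 22) and 1 in the wild type group. Per the labels, the cells were of the V6.5 line, of mixed 129 and C57BL6 background, were grown with leukaemia inhibitory factor on irradiated feeder cells, and were preplated before RNA extraction. The labels do not say whether the knockout samples are separate lines, clones or cultures, and the series' short design text speaks of mice. The p-values of single genes therefore measure only the spread between these samples, which may be technical.

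The deposited scanner files hold spot intensity values made with Agilent Feature Extraction version 10.1.1.1, per the file headers. The processed intensity of each spot had been background-subtracted and detrended within its array, with dim values replaced by surrogates, per the file headers. No scaling between arrays had been done on it. The deposited series matrix holds log2 values of the same arrays. Its 3 columns each have a median of 5.52 and correlate at 0.991 to 0.993 with the log2 mean spot intensity, so its scale is log2 and its columns share 1 median. Whether its background was corrected stays unknown. The submitters' processing notes name limma, without a version.

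Each file lists 45018 spots, of which 43379 are not controls. On the 3 arrays 62.2% to 62.8% of these were well above background by the scanner software's flag, and 0 were saturated. The 75th percentile of the processed intensity was 717.7 on KO 4, 644.9 on KO 22 and 623.7 on the wild type array. All 3 arrays lie on 1 slide and were scanned in 1 run, so slide and scan did not differ between the groups. The number of arrays limits the precision.

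The main values were log2 of the processed intensity minus each array's 75th percentile over non-control spots. Spots with an outlier flag were left out, and repeated spots of a probe were averaged. The files hold 41174 probes, and 32737 of them (79.5%) were matched to a gene of the reference table (assembly GRCm38.p6) by accession, symbol or synonym. Other probes kept the name in the file. The reference table served for names and chromosomes only, and probe positions are those in the files, on build mm7. A probe was tested if it was well above background on at least 1 array, and the probe with the highest mean represented its gene, which left 17708 genes.

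The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with Benjamini-Hochberg adjustment and a threshold of 0.05. The fit has 1 residual degree of freedom per gene, from the pair of knockout arrays, and 3.03 after moderation. The lone wild type array is assumed to vary like them. Beside the test, genes at least 2-fold apart from wild type on both knockout arrays were counted, and the same count was made with each knockout array in turn as the lone array. A gene not well above background on every array of 1 genotype has only a lower bound. The bound sets the bright group's mean against, per dim array, the higher of the gene's own value and the lowest value among probes well above background there, and it is written as at least N-fold.

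For the 19 gene lists, limma's camera was run with a preset correlation of 0.01 and again with an estimated correlation. The median of each list was ranked among 10000 random lists of the same size matched on mean level. Differences of both knockout arrays share the wild type array, so their correlation was set beside 100 simulated sets of 3 unchanged arrays. Chromosome medians have 95% bootstrap intervals from 1000 draws over genes, which cover the spread of genes and not of samples.

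The gene lists, the tests, the rule for named genes and most alternatives were fixed before the data were examined. The text names Tet1, Tet2, Tet3, Pou5f1, Sox2 and Nanog first. Next come the 12 largest rises and the 12 largest falls past the threshold among genes well above background on all 3 arrays, with both knockout arrays on the same side of wild type. Where fewer passed, the genes with the largest smaller-of-both difference filled the places, and the text says that these did not pass. Then follow the 4 genes with the largest bound in each direction and up to 4 members of each list by size of the mean difference. Predicted genes, clones and transcript names were counted but not named.

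The steps were tested on simulated arrays with the spread of the real ones and 200 changed genes among 17708. Of the 67 genes changed by 1 on the log2 scale limma called 0, of the 67 changed by 2 it called 0, and of the 66 changed by 4 it called 46, so the test has little power below large changes at this sample size. Of the 17508 unchanged genes it called 0. With an intensity trend in eBayes the calls were 29, 53 and 59, with 5 unchanged genes called. A list of 25 genes shifted by 0.8 had p = 2.53e-37 in camera with the preset correlation and 0.0623 with an estimated one, by limma on 1 residual degree of freedom. The real arrays differ from this setting, with 4993 genes at an unadjusted limma p below 0.05 and Rhox5 called at a difference of 2.23. The simulated power and count of false calls may therefore not carry over to them.

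Alternatives were normexp background correction (offset 50) on the mean and local background intensities, quantile normalization, the series matrix values, no filter on dim probes, a filter requiring all 3 arrays, the mean over a gene's probes, an intensity trend with and without robust moderation, and each knockout array left out. After the data were seen, 2 more were added. One was normexp fitted without spots dimmer than their local background. The other left out spots bright on 1 array only that lie next to another such spot on the same array. No file was left out.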

Results

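The series profiled RNA of mouse ES cells labelled as knockouts of Tet1, an enzyme that oxidises 5-methylcytosine in DNA, beside wild type cells of the same named line. There were 2 knockout samples (KO 4 and KO 22) and 1 wild type sample, with 1 array each, and the wild type group has no replicate. Values are log2 processed intensities relative to each array's 75th percentile, and differences are knockout minus wild type. Errors of gene differences are standard errors from limma with n = 2 against 1. Moderation draws the spread of every gene toward a shared prior (SD 0.09). An error of 0.09 is therefore a shared minimum for genes on which the knockout arrays agree closely. It is not a precision measured for each gene, and no spread of wild type was measured. On the arrays of KO 4, KO 22 and wild type 27113, 27260 and 26993 of the 43379 non-control spots were well above background.

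The first comparison asks which transcripts differ in the ES cells labelled as Tet1 knockouts. The probe for Tet1 gave a processed intensity of 214 on KO 4 and 195 on KO 22 against 721 on the wild type array. Its difference was -1.94 ± 0.09, a 3.85-fold lower level that missed the threshold (limma adjusted p = 0.0529). It passed where only probes above background on all 3 arrays were tested (adjusted p = 0.0293) and in the series matrix values (-1.89, adjusted p = 0.0149), with a range of adjusted p over all alternatives from 8.16e-12 with normexp background correction to 0.17 without a filter. The probe (AK010953) lies on chromosome 10 from 62332082 to 62332141 on build mm7. Its place relative to the deleted part of the gene is not given in the sources used here, so it may check neither the deletion nor the labels. The p-values of single genes, here and in all that follows, measure only the spread between the knockout samples. The labels do not say whether these are separate cultures. The other members of the family differed less, with -0.25 ± 0.09 for Tet2 (adjusted p = 0.204) and -0.07 ± 0.21 for Tet3 (adjusted p = 0.849), whose sign differed between the knockout arrays.

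The core pluripotency transcripts were present on every array, with an intensity of 21200, 19000 and 25400 for Pou5f1, which encodes Oct4, on KO 4, KO 22 and wild type. Pou5f1 differed by -0.47 ± 0.09 (adjusted p = 0.117), Sox2 by -0.04 ± 0.09 (adjusted p = 0.78) and Nanog by 0.25 ± 0.12 (adjusted p = 0.269). None of these 3 passed in the main test. The difference of Sox2 turned to 0.01 with quantile normalization and 0.02 in the series matrix values. With normexp as planned, which 8 spots of the wild type array distorted, Sox2 turned to 0.46 and Pou5f1 to 0.09. Without those spots Pou5f1 stood at -0.44 and passed (limma adjusted p = 0.00752). With an intensity trend Pou5f1 passed (limma adjusted p = 0.0132), while Sox2 and Nanog did not (0.717 and 0.102).

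Among genes above background on all 3 arrays, 2 rose and 8 fell. Rhox5, an X-linked homeobox gene, rose by 2.23 ± 0.09 (4.69-fold, adjusted p = 0.0426), and Septin4, which encodes a filament-forming GTPase, rose by 2.45 ± 0.10 (5.47-fold, adjusted p = 0.0426). The largest fall was that of the Y-linked translation factor gene Eif2s3y, at -5.63 ± 0.19 (49.5-fold, adjusted p = 0.0346). Its intensities of 17.3 on KO 4 and 19.8 on KO 22 lay near the lowest ones well above background there (11.28 and 9.86). The size of this fall is therefore uncertain. Plagl1, an imprinted zinc-finger gene, fell by -3.52 ± 0.10 (11.5-fold), and the water channel gene Aqp8 fell by -3.67 ± 0.10 (12.7-fold), both with an adjusted p of 0.0346. Cubn, the endocytic receptor cubilin, fell by -3.46 ± 0.11 (11-fold, adjusted p = 0.0346). Srgn, the proteoglycan serglycin, fell by -3.44 ± 0.14 (10.8-fold, adjusted p = 0.0443). The X-linked, lymphocyte-regulated family members Xlr3c and Xlr4b fell by -3.07 ± 0.09 and -2.90 ± 0.09 (both adjusted p = 0.0346), and their near-identical copies can share probe signal. Tgtp1, an interferon-inducible GTPase, fell by -2.21 ± 0.09 (adjusted p = 0.0426), but averaged over its 2 probes the difference was -1.13 and did not pass (adjusted p = 0.0965). Srgn was not called after quantile normalization (adjusted p = 0.0595), and Rhox5, Septin4, Srgn and Tgtp1 narrowly missed the threshold without clustered spots bright on 1 array (adjusted p = 0.0505 each). On build mm7 the probes of Plagl1 and Srgn lie on chromosome 10, at 12831831 to 12831890 and 62013209 to 62013268. Those of Xlr4b and Xlr3c lie on chromosome X, at 68609046 to 68609105 and 68641591 to 68641650.

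The places left were filled with genes that did not pass. The growth factor gene Igf2 had a difference of 2.21 ± 0.12 (adjusted p = 0.0612), and the iron exporter gene Slc40a1 one of 1.95 ± 0.09 (adjusted p = 0.0538). The other 8 with higher values were Ido2, Vnn1, Kirrel, Ccdc184, Wnt7a, Anxa3, Rab6b and Klhl13, with mean differences from 1.75 for Klhl13 to 2.67 for Ido2, of which Vnn1, Ccdc184 and Wnt7a turned to -1.34, -0.76 and -1.37 with normexp as planned. On the lower side stood the germline gene Fkbp6 at -3.71 ± 0.38 (adjusted p = 0.0971) and the piRNA pathway gene Piwil4 at -2.79 ± 0.13 (adjusted p = 0.0522). Zscan4c and Tcstv1, which mark a state of ES cells resembling the 2-cell embryo, stood at -2.82 ± 0.27 and -2.69 ± 0.18.

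Some genes were not well above background in 1 genotype and have only bounds. The Y-linked RNA helicase gene Ddx3y was at least 19.6-fold lower in both knockout arrays (adjusted p = 0.0346), and Xlr5d at least 20.3-fold lower (adjusted p = 0.0426, but 0.0687 with quantile normalization and 0.0505 without clustered spots bright on 1 array). Olfr550, an olfactory receptor gene, was at least 10.9-fold lower (adjusted p = 0.0346), with 5 spots bright on the wild type array alone within 2 rows and columns of its own spot. Ifi203, an interferon-inducible gene, was at least 14.5-fold lower and did not pass (adjusted p = 0.101). On the higher side A2m, a protease inhibitor gene, was at least 9.36-fold higher (adjusted p = 0.039), and Abhd3, a phospholipase gene, at least 5.11-fold higher (adjusted p = 0.0346). Syt1 was at least 3.45-fold and Ripor3 at least 3.33-fold higher, and neither passed (adjusted p = 0.212 and 0.0971). The Syt1 bound is for the knockout mean and leans on KO 4. Against the dim wild type value itself Syt1 was 7.96-fold higher on KO 4 but only 2.59-fold on KO 22. The A2m spot lay beside 1 spot bright on the wild type array alone. With normexp as planned, which 8 spots of the wild type array distorted, A2m and Abhd3 turned to -0.99 and -1.44; without those spots they stood at 1.18 and 0.84.

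In all, limma called 63 of 17708 genes, 6 higher and 57 lower in the knockout samples. Of the 57, 49 were below background on both knockout arrays, and 27 of these 49 lay beside a spot that was bright on the wild type array alone. Dim values can be surrogates, so for these 49 genes agreement of the knockout arrays may reflect the floor rather than replication. The SD between the knockout arrays was 0.07 for Olfr550 and 0.05 for Zfp352, but 0.25 for Ddx3y and 0.29 for Xlr5d. Both knockout arrays lay at least 2-fold above wild type for 256 genes and at least 2-fold below it for 277. These counts were 109 and 180 in the series matrix values, 152 and 131 with a filter requiring all 3 arrays, 57 and 52 with normexp without the 8 distorting spots, and 104 and 5655 with normexp as planned. The same rule gave 103 genes with KO 4 as the lone array and 102 with KO 22, and 533 with wild type. The samples allow only 3 choices of a lone array. The count of calls changed with the variance model, the filter and the values used. An intensity trend in eBayes called 1473 higher and 1900 lower, a filter requiring all 3 arrays called 500 and 412, and the series matrix values gave 476 and 493. Normexp called 5211 and 8630 as planned and 1365 and 1869 without the 8 spots. Without clustered spots bright on 1 array, an alternative chosen after seeing the data, limma called 4 higher and 25 lower. Without a filter limma called 0 of 27650 genes, with 5969 at an unadjusted p below 0.05.

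**Figure D1:**
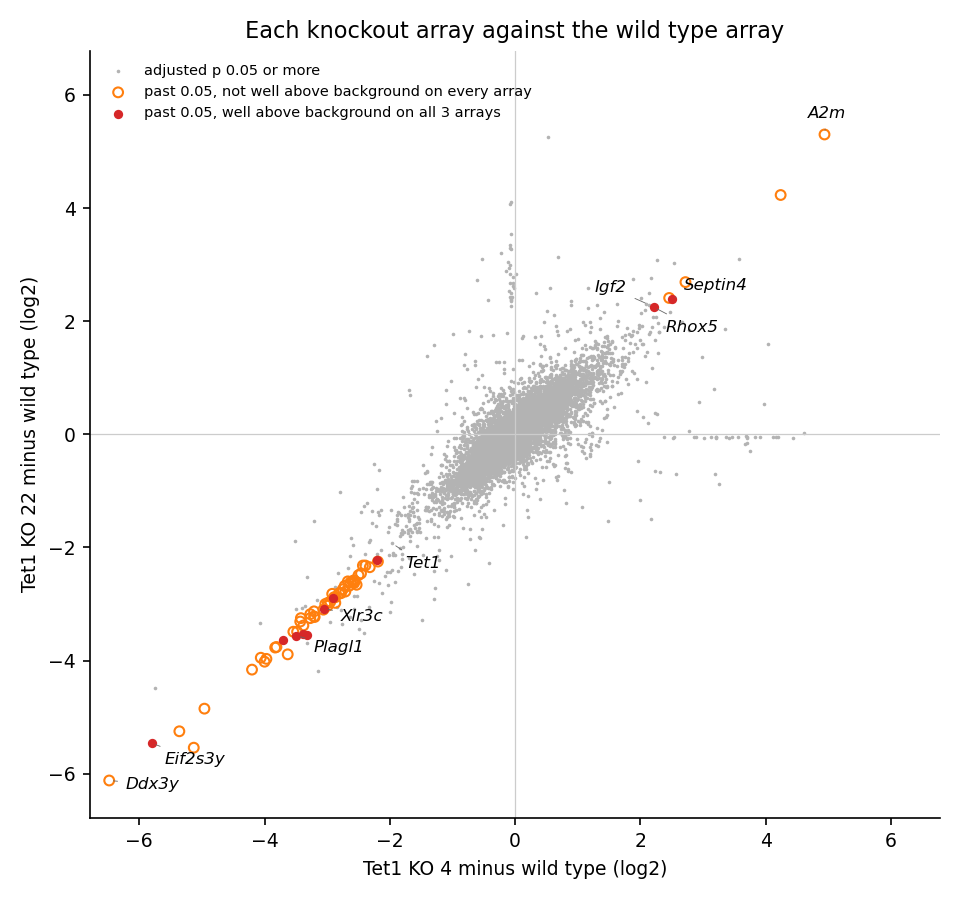
Each point is 1 of 17708 genes, with the log2 difference of KO 4 from wild type on the horizontal axis and that of KO 22 on the vertical axis; red points passed an adjusted p of 0.05 and were well above background on all 3 arrays, orange circles passed without that, and grey points did not pass. The 63 genes that passed lie near the diagonal, with Ddx3y, at background on both knockout arrays, at -6.48 and -6.12 and Rhox5 at 2.21 and 2.25, while strips of grey points along either axis stand for genes far from wild type on 1 knockout array alone.

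The knockout samples resembled each other more than either resembled wild type. The standard deviation of the log2 difference over genes was 0.33 between KO 4 and KO 22, 0.53 between KO 4 and wild type, and 0.52 between KO 22 and wild type. Between the knockout arrays 137 genes were at least 2-fold higher in KO 4 and 114 at least 2-fold lower, with 1 array each and no test. The collagen gene Col3a1 lay 1.21 above KO 22 in KO 4, and Col1a2 and Col1a1, at 0.80 and 0.79, stayed below 2-fold. Across genes, which are not independent replicates, the differences of both knockout arrays from wild type correlated at r = 0.80. Unchanged arrays sharing 1 wild type array gave r = 0.50 in simulation. The covariance was 0.219 against 0.056 simulated, a difference of 0.164, and 83.5% of genes had the same sign against 66.7% simulated. Part of the excess may come from the shared array, since 1 wild type array cannot be split.

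Gene lists fixed beforehand tested whether markers of lineages and states that ES cells can enter shifted together. Of the 19 lists 8 passed with the preset correlation of 0.01. Those list p-values rest on the spread across genes and on that preset, not on the spread between samples. In the lists that passed, the estimated correlation ran from -0.03 for mesendoderm to 1.00 for Y-linked genes, with 0.77 for fibroblast. Trophoblast, mesendoderm, fibroblast and immediate early lists rose and 2-cell-like, primitive endoderm, germline and Y-linked lists fell, while the pluripotency list did not pass. With an estimated correlation limma's camera passed 0 of the 19 lists, at a lowest adjusted p of 0.696. The estimated correlation was run on the values as reported and not on the alternatives. By their medians, 13 lists lay outside the central 95% of random lists. Besides the lists that passed, these were primed epiblast and interferon (percentile 0 each), neuroectoderm (1.34), pluripotency (1.42) and p53 (98.15). Random lists ignore correlation between members, estimated at 0.62 for primed epiblast.

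Of 23 measured trophoblast markers, 21 were higher on both knockout arrays and 2 lower. The list rose, with a median difference of 0.75 on KO 4 and 0.84 on KO 22 (camera adjusted p = 3.91e-08, and adjusted p = 0.696 with an estimated correlation). Adjusted over the list alone 15 members were higher and 1 lower; over all genes limma called 0, with 16 higher and 1 lower at an unadjusted p below 0.05 and 16 higher called with an intensity trend. The homeobox genes Rhox6 and Rhox9 stood at 1.82 ± 0.20 and 1.42 ± 0.18, the transcription cofactor gene Cited1 at 1.47 ± 0.09, and Eomes, a T-box regulator of trophoblast and mesendoderm, at 1.27 ± 0.13, or -0.75 with normexp as planned. None of the 4 passed over all genes.

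Of 22 primitive endoderm markers, 13 were lower on both arrays and 5 higher, and the list fell, with medians of -0.42 and -0.49 (camera adjusted p = 0.005, and adjusted p = 0.696 with an estimated correlation). Cubn and Srgn passed over all genes, and 10 members were lower and 1 higher adjusted over the list alone. The endoderm transcription factor genes Foxa2 and Sox17 had differences of -1.63 ± 0.12 and -1.36 ± 0.09 (adjusted p = 0.0818 and 0.0742). The list did not pass with normexp as planned (median -1.20, adjusted p = 0.0891).

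The 2-cell-like list fell too, with 7 of 8 measured members lower on both arrays and medians of -2.04 and -2.38, or -1.38 for the mean difference with the dim gene at its bound (camera adjusted p = 0.0015, and adjusted p = 0.696 with an estimated correlation). Zfp352 passed over all genes (adjusted p = 0.0426) with both knockout arrays at background, and was at least 1.18-fold lower; it missed the threshold in the series matrix values (adjusted p = 0.0849) and without clustered spots (0.0505). Adjusted over the list alone 5 members were lower. Usp17la stood at -2.34 ± 0.33. Without a filter on dim probes the median was -0.47. Zscan4c, Tcstv1 and Usp17la belong to multicopy families whose members can share probe signal.

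Of 34 germline genes, 23 were lower on both arrays and 7 higher. The list fell, with medians of -0.38 and -0.22 (camera adjusted p = 0.005, and adjusted p = 0.696 with an estimated correlation), and 13 members were lower and 2 higher adjusted over the list alone. With normexp as planned it did not pass (adjusted p = 0.0688). The only member called over all genes was Rhox5, which rose. Lower values were those of Fkbp6, of the dipeptidase gene Dpep3 at -1.92 ± 0.37 and of Slc25a31, a testis ADP/ATP carrier gene, at -1.25 ± 0.09.

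Of 17 mesendoderm and mesoderm markers, 12 were higher on both arrays and 4 lower. The list rose, with medians of 0.36 and 0.35 (camera adjusted p = 0.0115, and adjusted p = 0.696 with an estimated correlation), but with normexp background correction as planned it passed in the opposite direction, with a median of -1.35 (adjusted p = 0.0346), and the median was 0.10 once 8 spots dimmer than their background were left out. No member passed over all genes in limma or adjusted over the list alone, and 8 were higher and 2 lower at an unadjusted p below 0.05. An intensity trend called 4 higher and 1 lower. The signalling genes Wnt3 and Fgf8 stood at 1.73 ± 0.35 and 1.48 ± 0.26, T (brachyury) at 1.04 ± 0.28, or -1.71 with normexp as planned, and the Wnt target Sp5 at 0.97 ± 0.21.

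The fibroblast list was included because the cells grew on feeders. It rose, with 17 members higher and 4 lower on both arrays (camera adjusted p = 0.0115, and adjusted p = 0.779 with an estimated correlation), but its 34 members had a median of 0.67 on KO 4 and 0.01 on KO 22, so the shift rested on 1 array. The median was -0.02 with normexp as planned and 0.16 with normexp without the 8 spots. Limma called 0 members over all genes, 0 adjusted over the list alone, and 5 higher and 1 lower at an unadjusted p below 0.05. An intensity trend called 5 higher and 1 lower. Anxa1, Tagln and Thbs1 stood at 1.57 ± 0.24, 1.47 ± 0.29 and 1.20 ± 0.21, and Cav1 at 0.87 ± 0.37. Unlike the list median, the first 3 were at least 2-fold higher on both knockout arrays. Their differences were 1.80, 1.74 and 1.39 on KO 4 and 1.35, 1.19 and 1.00 on KO 22.

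The list of immediate early and heat shock genes rose, with medians of 0.37 on KO 4 and 0.15 on KO 22 (camera adjusted p = 0.0115, and adjusted p = 0.696 with an estimated correlation). Of 20 members 14 were higher on both arrays and 4 lower, and 3 were higher adjusted over the list alone. Fos and Jun, subunits of the AP-1 transcription factor, stood at 1.04 ± 0.16 and 0.90 ± 0.11, Ccn1 at 0.73 ± 0.10 and Fosb at 0.57 ± 0.25. Limma called 0 of them over all genes, with 6 higher and 1 lower at an unadjusted p below 0.05 and the same numbers with an intensity trend.

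The Y-linked list fell, with medians of -3.72 and -3.34 over 4 measured genes, or -2.86 for the mean difference with Ddx3y at its bound (camera adjusted p = 0.0115, and adjusted p = 0.696 with an estimated correlation). Ddx3y and Eif2s3y passed, and 3 members were lower adjusted over the list alone. Uba1y had differences of -1.64 and -1.22 (adjusted p = 0.106), and Zfy1, which has close relatives elsewhere in the genome, had -0.04 and 0.42 (adjusted p = 0.642), or -1.77 with normexp as planned. In the 3 genes above background on every array the list median was -1.43 and did not pass (adjusted p = 0.0761).

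The other lists did not pass, although alternatives given here passed some of them. Adjusted over the list alone, 1 member was higher and 6 were lower among 19 neuroectoderm genes, 2 and 4 among 20 primed epiblast genes, and 1 and 3 among 22 genes of the methylation machinery. The same adjustment gave 1 and 2 among 17 Nodal and Lefty genes and 3 and 1 among 43 imprinted genes, while 1 Hox gene and 3 of 21 interferon genes were lower. Over all genes limma called Plagl1 alone in these lists. Adjusted over the list alone limma called 0 members of the pluripotency, p53, hypoxia and ribosomal lists. At an unadjusted p below 0.05 these 4 lists had 2 higher and 10 lower, 3 and 2, 2 and 2, and 1 and 0, and the counts with an intensity trend were the same. Of 32 pluripotency genes 19 were lower and 8 higher on both arrays, with a median of -0.16 (camera adjusted p = 0.121). Its largest differences were those of Dppa3 at 0.99 ± 0.09, Nodal at -0.56 ± 0.11, Tbx3 at -0.50 ± 0.09 and Esrrb at -0.47 ± 0.09. With normexp as planned the median turned to 0.38 and passed (camera adjusted p = 5.44e-06). The estimated correlation was run on the main values only, where the median was -0.16, and gave a camera adjusted p of 0.696. In the Nodal and Lefty list (median -0.13, adjusted p = 0.483) Lefty1 and Lefty2, which encode Nodal inhibitors, stood at -1.02 ± 0.16 and -0.58 ± 0.11. Smad7, which encodes an inhibitor of the pathway, stood at 1.11 ± 0.11. In the list of the DNA methylation machinery (median -0.17, adjusted p = 0.293) Dnmt3a, a de novo methyltransferase, stood at -1.13 ± 0.17, Gadd45a at 0.82 ± 0.09 and Sin3a at -0.60 ± 0.09. In the primed epiblast list (median -0.34, adjusted p = 0.416) Otx2 and Fgf15 stood at -2.03 ± 0.14 and -1.92 ± 0.13, and Car4 at 1.09 ± 0.16. In the neuroectoderm list (median -0.22, adjusted p = 0.0589) Pax6 stood at -1.71 ± 0.20 and Lhx2 at 0.96 ± 0.09. Neurod1 was at least 2.93-fold lower. Dcx was above background on KO 22 alone, so its differences of 0.69 and 3.13 rest on a wild type value at background and have no firm size. The neuroectoderm list passed with quantile normalization (adjusted p = 0.0264), the series matrix values (0.0165), normexp as planned (0.00118), normexp without the 8 spots (0.0151) and without clustered spots (0.0286). On the main values its camera adjusted p with an estimated correlation was 0.696.

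Among 43 imprinted genes the differences went both ways (median -0.10, adjusted p = 0.274). Plagl1 fell as given above, Igf2 had a difference of 2.21 ± 0.12, and H19, the noncoding RNA next to Igf2, had -1.21 on KO 4 and -2.05 on KO 22. Peg12 stood at 0.98 ± 0.11. Of 39 Hox genes in the list, 15 were measured (median -0.05, adjusted p = 0.642), with Hoxb13 at -1.75 ± 0.18 and Hoxb7 at -0.99 ± 0.31. Hoxc13 was above background on KO 22 alone, and Hoxa6 was at background on KO 22. The Hox list passed with normexp as planned (camera adjusted p = 7.72e-05). On the main values its camera adjusted p with an estimated correlation was 0.779. The interferon list had a median of -0.35 (adjusted p = 0.0589, and adjusted p = 0.699 with an estimated correlation). It passed with quantile normalization (adjusted p = 0.0458), the series matrix values (0.0291), the mean over probes (0.0469), normexp without the 8 spots (0.0088) and without clustered spots (0.0312). Oasl2 and Oas1a stood at -1.42 ± 0.21 and -0.70 ± 0.10, Rsad2 was at background on KO 22, and Ifi44 was above background on KO 4 alone. The p53 list (median 0.08, adjusted p = 0.293) held Perp at 0.97 ± 0.13, Tnfrsf10b at 0.57 ± 0.14, Tigar at -0.46 ± 0.13 and Sesn2 at -0.41 ± 0.09. It passed with normexp as planned (camera adjusted p = 4.85e-05) and without the 8 spots (0.0461). On the main values its camera adjusted p with an estimated correlation was 0.696. The hypoxia and glycolysis list (median -0.05, adjusted p = 0.933) held Pfkp at -0.70 ± 0.11, Vegfa at 0.60 ± 0.10, Ankrd37 at -0.45 ± 0.09 and Slc2a3 at 0.35 ± 0.09. The ribosomal protein list had a median of -0.05 (adjusted p = 0.711), with Rpl4 at 0.31 ± 0.09, Rps15 at 0.29 ± 0.12, Rpl3 at -0.27 ± 0.13 and Rps16 at -0.18 ± 0.21. The medians of the hypoxia and ribosomal lists turned to 0.02 and 0.00 with quantile normalization. With normexp as planned they turned to 0.46 and 0.50, and both passed (camera adjusted p = 6.98e-06 and 1.51e-10). On the main values the camera adjusted p with an estimated correlation was 0.947 for each. Normexp as planned also turned the methylation machinery and Nodal and Lefty medians to 0.16 and 0.03. Among the members named it turned Tbx3, Esrrb, Sesn2, Rpl3 and Rps16 to 0.01, 0.08, 0.21, 0.27 and 0.32, and Lhx2, Dcx, Hoxc13 and Ifi44 to -0.80, -1.84, -2.01 and -1.95.

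**Figure D2:**
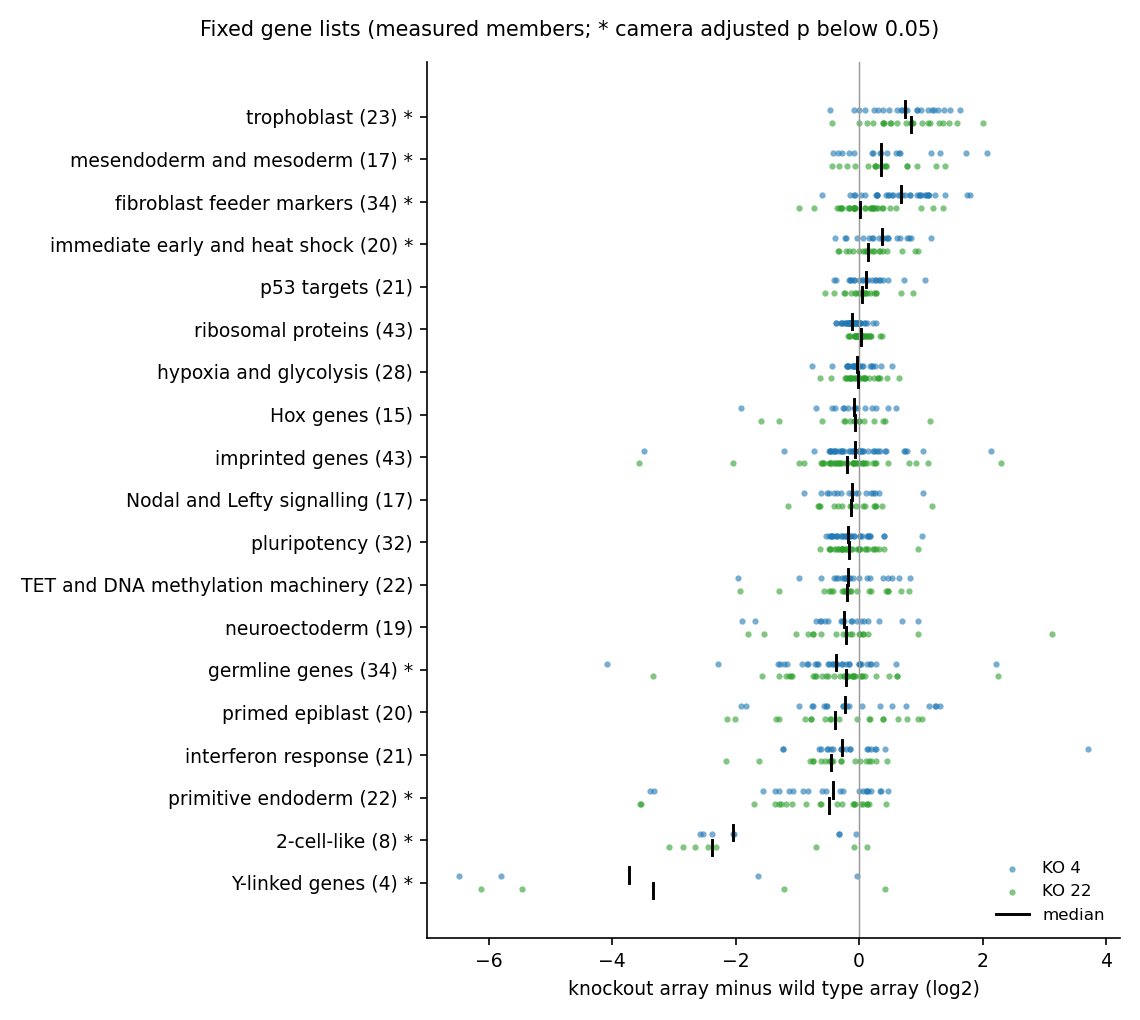
Each dot is 1 measured member of a fixed gene list, by its log2 difference from wild type on KO 4 (blue) or KO 22 (green), black bars are medians per array, the number of measured members follows each name and a star marks a camera adjusted p below 0.05. Trophoblast medians lie at 0.75 and 0.84 and 2-cell-like medians at -2.04 and -2.38, whereas the fibroblast medians part at 0.67 on KO 4 and 0.01 on KO 22.

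Chromosome medians asked whether either knockout sample had gained or lost a whole chromosome. Autosomal medians lay between -0.15 and 0.01 on KO 4 and between -0.12 and 0.02 on KO 22. The lowest was that of chromosome 7, at -0.15 (95% bootstrap interval -0.16 to -0.13, 1190 genes) on KO 4 and -0.12 (-0.13 to -0.10) on KO 22. The X chromosome median was -0.04 on both arrays over 490 genes. The Y chromosome, with 5 measured genes, had medians of -1.64 (-6.48 to 1.15) and -1.22 (-6.12 to 0.92), intervals that span 0. Its gene outside the fixed list, Rbmy, named here after its values were seen, was above background on both knockout arrays and at background on wild type, at least 1.26-fold higher (adjusted p = 0.102). The median over genes of KO 4 minus KO 22 lay between -0.01 and 0.01 on each autosome.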

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

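The alternatives added after the data were seen are normexp without 8 spots and the removal of clustered spots bright on 1 array. No paired analysis was possible because the groups share no replicate number. Leaving out either knockout array leaves 1 array against 1, so limma's counts have no value there; genes 2-fold higher then numbered 423 to 486 and genes 2-fold lower 381 to 388. Directions held for every named gene and list median in all alternatives with a test except those given here. Normexp as planned reversed 28 of them. On the wild type array 8 spots lay below their local background, by up to 8800, and moved the fitted background mean to -323, against 4.90 and 4.28 on KO 4 and KO 22. Without these spots it was 3.84, and no direction was reversed.

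With normexp as planned 5211 genes were called higher and 8630 lower, 104 were 2-fold higher and 5655 lower, and the correlation r of both knockout arrays' differences across genes was 0.99. The median of all genes shifted from -0.03 to -0.20. List medians turned to 0.16 for the methylation machinery, 0.38 for pluripotency, 0.03 for Nodal and Lefty, -1.35 for mesendoderm, -0.02 for fibroblast, 0.46 for hypoxia and 0.50 for ribosomal proteins. Genes that turned lower were Vnn1 (-1.34), Ccdc184 (-0.76), Wnt7a (-1.37), A2m (-0.99), Abhd3 (-1.44), Syt1 (-1.63), Ripor3 (-1.62), Eomes (-0.75), T (-1.71), Dcx (-1.84), Lhx2 (-0.80), Hoxc13 (-2.01), Ifi44 (-1.95) and Zfy1 (-1.77). Genes that turned higher were Pou5f1 (0.09), Sox2 (0.46), Tbx3 (0.01), Esrrb (0.08), Sesn2 (0.21), Rpl3 (0.27) and Rps16 (0.32). Without the 8 spots, normexp called 1365 higher and 1869 lower, with 57 genes 2-fold higher and 52 lower and r = 0.88; its offset draws dim genes together.

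Quantile normalization turned hypoxia to 0.02, ribosomal proteins to 0.00 and Sox2 to 0.01, and moved the medians of chromosomes 1 and X to 0.02 and -0.02. The series matrix values turned the same items to 0.00, 0.03 and 0.02. They called 476 genes higher and 493 lower, with 109 and 180 2-fold apart. Without a filter 0 genes were called either way by limma, with 385 and 521 2-fold apart; more genes were tested, of which 5969 had an unadjusted p below 0.05. The filter on all 3 arrays called 500 and 412, with 152 and 131 2-fold apart, r = 0.88 and an X median of -0.04. The intensity trend called 1473 and 1900, and 1541 and 2024 with robust moderation. Without clustered spots 4 genes were called higher and 25 lower. Lists past the threshold numbered 8, against 0 with an estimated correlation (camera, 19 lists), which has little power here. The median of 13 lists lay outside the central 95% of random lists. The cause of the other changes was not tested. Over the 8 alternatives that change values, filter or probes and have a test, 526 of 798 values of named genes kept their direction and side of the threshold, 223 newly passed, 26 no longer passed and 23 were reversed; the intensity trends are not among these, and with a trend Tet1, for example, passed (adjusted p = 9.59e-04). For lists the numbers were 125 of 152, 13, 3 and 11. Signal near background limits the size of any fall to it.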

Other observations

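All tests of explanations in this part were chosen after the result was seen, as were the gene families and the region around Tet1 described here.

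All 4 measured genes of the X-linked Xlr family were lower on both knockout arrays, and 3 passed, with Xlr5d at least 20.3-fold lower; Xlr5c, which did not pass, was at least 5.25-fold lower, both at background on both knockout arrays. Of 6 measured Rhox genes, also X-linked, 3 were higher on both arrays and 3 lower. Rhox5 rose, Rhox6 and Rhox9 had higher values, and Rhox13 had differences of -0.93 and -1.14 (adjusted p = 0.101). Directions of Xlr3c, Xlr4b, Xlr5d, Rhox5, Rhox6 and Rhox9 held in every alternative with a test, and those of the other members were not examined there. Slfn8 passed as well, at least 2.69-fold lower with both knockout arrays at background, whereas Slfn9 had 0.17 and -0.17. Of 4 Pramel genes 2 were lower and 1 higher on both arrays, and Pramel37 passed (adjusted p = 0.0346), at background on both knockout arrays, while Pramel13 stood at 0.43. Of 4 genes of the Ifi200 family 2 were higher on both arrays and 1, Ifi203, lower (adjusted p = 0.101). No family was tested as a set.

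Within 1 Mb of the Tet1 probe 25 other genes were measured, 14 higher and 8 lower on both knockout arrays, with a median difference of 0.12. Only Srgn passed, 319 kb away, and 1 more gene was 2-fold apart on both arrays, Hkdc1 at 430 kb with -1.67 and -1.42 (adjusted p = 0.0971). The genes nearest to the probe on either side that have a gene symbol, Ccar1 at 60 kb and Slc25a16 at 132 kb, had mean differences of 0.16 and -0.20.

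Many called falls may come from the surface of the wild type array rather than from the cells. Of 204 spots bright on the wild type array alone, 98 had another within 2 rows and columns, against 21 on average and at most 36 in 200 random placements. Of the 49 called genes below background on both knockout arrays 27 lay beside such a spot, against a mean of 4.1 and a maximum of 11 in 1000 random sets. The random sets came from all spots well above background on at least 1 array, whereas the 49 genes were above it on wild type alone. That comparison therefore largely repeats the clustering of such spots. Uncalled genes of the same kind were not compared, so it cannot show that the calls favour clusters. KO 4 and KO 22 held such clusters too, with 54 of 99 and 37 of 94 spots. Of the 8 genes called lower and above background on all 3 arrays 0 lay beside a spot bright on wild type alone. The random mean was 0.7 and the maximum 4, so no clustered blemish was seen beside them. They differed from the 27 of 49 (Fisher's exact two-sided p = 0.00489). The 49 were above background on wild type alone and share the clustering of such spots, whereas the 8 were not chosen that way. That p-value therefore cannot exclude blemishes among the 8. A blemish on a single spot and the genotype stay open for them, as they do for the 22 genes not beside one.

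Ddx3y and Eif2s3y fell in both knockout samples, so the sex chromosomes may differ along with the genotype. The values argue against 2 active X chromosomes in the knockout cells, since the X-linked median exceeded the autosomal one by 0.01 (bootstrap interval -0.02 to 0.04). None of the 4 Xist probes was well above background on any array, wild type included, so Xist did not tell the groups apart and adds nothing to this argument. Of 4 Y-linked genes above background in wild type, 3 were at least 2-fold lower on both knockout arrays, Uba1y among them without passing, while Rbmy was above background on both knockout arrays alone, with dim intensities of 15.4 and 11.8 against 6.02. Absence of a Y chromosome cannot be told apart from a lower level of a few of its genes, because the Zfy1 probe did not fall. The Rbmy probe was at background on wild type and so could not have fallen. Its intensities on KO 4 and KO 22 lay near the lowest ones well above background there (11.28 and 9.86). Other genes cannot be ruled out as a source of the signal of either probe, and an effect of Tet1 itself stays untested.

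Fibroblast markers were higher in KO 4 than in KO 22, with 32 of 34 members and a median of 0.59. RNA of feeder fibroblasts may have entered the KO 4 sample, although the cells were preplated. The median lay above all 10000 random lists, which restates the difference and does not show its source. Col3a1, Postn, Col1a2 and Bgn stood 1.21, 1.19, 0.80 and 0.80 higher. Fn1, Vim and Sparc, the last from the primitive endoderm list, stood only 0.08, 0.18 and 0.04 higher. Their wild type intensities were 4900, 7280 and 5980. Whether such levels hid a small share of feeder RNA was not tested, and Tagln, at 5090 on wild type, stood 0.55 higher. All 34 members were above background in wild type, and Dcn is also on the imprinted list. More differentiated ES cells in KO 4 cannot be told apart from feeder RNA: the highest median of the trophoblast, primitive endoderm, mesendoderm and neuroectoderm lists was only 0.14, but primitive endoderm and mesendoderm, at 0.14 and 0.10, ranked at percentiles 99.97 and 98.52 of random lists, and members went both ways.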
